A study of Mus musculus with 8 samples.

How the data were processed

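Single-cell RNA was measured in 4 libraries of CD4 T cells sorted from mouse lung, 1 library for each combination of genotype (wild type, WT, or Batf3-deficient, KO) and fraction (CD45neg, not reached by the intravenous CD45 antibody, or CD45pos, labelled by it). The libraries were prepared with 10x Genomics 3′ v3 reagents and carried TotalSeq-A antibody tags against APC, PE, CD103, CD69, CD62L and CD44. According to the submitters' processing notes, the authors made the matrices with Cell Ranger 7.0.0 on the mm10 genome. The gene annotation they used is not given in the sources used here. The deposited matrices hold raw UMI counts (unique molecular identifiers, integers) per gene and barcode, and per the file headers they list 32285 genes and 7 tags. The 7th tag, streptavidin, is not in the labels and was 0 in every cell. Each matrix is deposited in a pair of copies whose entries were checked and are identical, so 1 copy was used. The 4 tag libraries have sample entries of their own without separate files, and their counts were read from the same matrices. For 1 of these entries, the tags of WT CD45pos, the genotype field holds a cell type, and its group was taken from its title.

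Cells were kept with at least 500 detected genes and at most 10% mitochondrial UMIs. Doublets were scored by the share of simulated doublets (2 per cell) among 90 neighbours. The scores did not fall into separate peaks, so the highest-scoring cells were removed at a rate of 0.8% per 1000 cells, a rule chosen after the scores were seen. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes without receptor, immunoglobulin, mitochondrial, ribosomal protein and sex-linked genes gave 30 principal components, and a shared-neighbour graph of 20 exact neighbours was clustered by Leiden at resolution 1 with a fixed seed. Cells of all libraries were clustered together. A cluster was named "-like" after a fixed marker list when members of that list, at least 1.5-fold higher there than in the other cells and at 5 CPM or more, stood among its 10 leading genes or ranked high. The other clusters kept their number, although some of them also had list members among their 10 leading genes. Cluster 18 had Il23r, Il1r1 and Il22 of the Th17 list there, and cluster 7 had genes of the Th1, CD8 T and NK lists. The names, the marker fold and the choice of which clusters hold T cells were made after the clusters were seen. Cells of the T-cell clusters were pooled per library and divided by the library's T-cell total (CPM).

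The comparisons, the alternatives, 31 gene lists and the rule for named genes were set before the data were examined. With 1 library per group there is no error between animals, so no test across samples and no p-value was computed. Ratios of pooled CPM carry exact conditional binomial intervals, shares of cells exact Clopper-Pearson intervals and single levels exact Poisson intervals, all at 95%. All of these cover counting error only, not the spread between mice, sorts or libraries. A gene or share is called higher or lower by the rule when its ratio is at least 1.5-fold and its interval excludes 1. Fold values are ratios of CPM, while log2 ratios have 1 CPM added to both values. A level of 0 is given with its 95% upper bound, and folds against 0 use a floor of 3 counts. For each comparison the 12 highest and 12 lowest genes by log2 ratio were named, among genes at 20 CPM or more in 1 of the libraries compared, leaving out receptor, immunoglobulin, mitochondrial, ribosomal protein and sex-linked genes. Within a class of at least 100 cells per library, the 5 highest and 5 lowest at 50 CPM or more were ranked. Batf3 and members of the lists were named in addition, and these names cover 67 genes by rank.

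A list was summarised by the median log2 ratio of its members at 5 CPM or more in 1 of the libraries, with an interval from 1000 Poisson draws. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, is given as a description of these libraries. The state lists were naive and central memory, tissue residency, Th1, Th2, Th17, Treg, Tfh, interferon response, proliferation, and immediate early and dissociation stress. Lists of other cell types were CD8 T, NK, gamma-delta T, ILC2, B, plasma, monocyte and macrophage, dendritic, neutrophil, mast and basophil, epithelial, endothelial, stromal, and erythroid and platelet. Further lists were Batf and partner factors, chemokine and homing receptors, costimulation and checkpoint, cytokine and alarmin receptors, glucocorticoid response, sex-linked, and distal chromosome 1 near Batf3. Gene positions are from the RefSeq annotation of GRCm38 and were found by symbol for 26259 of the 32285 identifiers. Some lists share genes, Gata3 and Il1rl1 standing in both the Th2 and the ILC2 list.

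Shares of cells with a UMI were taken after each cell was thinned to 2000 UMIs, leaving out shallower cells. Tag counts were compared as means and as shares of cells over 1 Otsu threshold per antibody. The alternatives were a looser cell filter (200 genes, 20%) and a stricter one (1000 genes, 5%), doublets kept, TMM scaling, every cell weighing the same, all cell types included, ranking at 50 CPM, list members at 20 CPM, resolutions 0.6 and 1.5, 15 components, thinned cells, other tag thresholds and all deposited barcodes. Added after seeing the data were pools without clusters 7, 15 and 18, genes without the cell holding most of their UMIs, Treg-like cells of cluster 12 alone, shares among T cells outside the naive-like clusters, and clustering without 58 genes (the residency list and 50 leading genes of the residency-like cluster). The bound of the distal part of chromosome 1, its count in naive-like cells and most tests of explanations were also chosen then.

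Libraries of these depths were also simulated with counting error only, for genes at 20 CPM or more. There, all genes set 2-fold or 4-fold apart passed the 1.5-fold rule and 0 unchanged genes did. The simulation held no spread between mice, sorts or cells and no genes with lower counts, so it gives no rate of false calls for these data. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 (TMM factors). No paired analysis was possible because the labels do not link the animals behind the libraries. Sequence reads were not analysed here, and some list members and 1 tag are not reported here.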

Results

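The data are UMI counts per gene and cell from CD4 T cells of the lungs of mice sensitized to house dust mite, an inhaled allergen, on days 0 and 7. After a further 5 weeks the sample labels give an allergen challenge, whereas the series description gives rest, and which of these held is not settled by the sources used here. Mice were wild type (C57B6/J, WT) or carried the B6.129S(C)-Batf3tm1Kmm/J allele (KO). Batf3 is a transcription factor needed for the development of type 1 conventional dendritic cells. An anti-CD45 antibody given into the blood labels circulating leukocytes, so that CD45pos cells come from the circulation and CD45neg cells from the tissue. The series title names the question, whether lung-resident memory CD4 T cells build up through these dendritic cells. Each of the 4 groups has 1 library, and the number of mice behind a library is not given in the sources used here. No difference in the text therefore has a replicate check.

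The libraries held 10455 barcodes (WT CD45neg), 11080 (WT CD45pos), 11702 (KO CD45neg) and 10266 (KO CD45pos). Their total UMI counts were 42833848, 61179869, 54735409 and 50539794 in the same order. After the cell filter and removal of called doublets, 9306, 9884, 10406 and 9236 cells remained, with median depths of 3726, 5038, 4269 and 4463.5 UMIs. WT CD45neg was thus the shallowest library and WT CD45pos the deepest. T cells numbered 9285, 9727, 10376 and 9129. The Y-linked gene Ddx3y lay between 90.1 and 100.5 CPM in all 4 libraries and Xist had at most 2 UMIs in any, and the sex-linked list had medians between -0.08 and 0.12 in the 4 comparisons.

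Batf3 itself (ENSMUSG00000026630, GRCm38 chromosome 1, 191098414 to 191108943) was close to absent from T cells of either genotype. It had 0, 1, 1 and 0 UMIs in the T cells of WT CD45neg, WT CD45pos, KO CD45neg and KO CD45pos, which bounds its level at 0.101, 0.106, 0.118 and 0.0842 CPM. A genotype difference in T cells was not detectable at this depth. The few cells of other types in the sorts did hold it. Macrophage-like cells had 34 Batf3 UMIs in 69 WT cells (74.1 CPM, 51.3 to 103.6) and 0 in 19 KO cells (upper bound 25.9 CPM), where the WT level would give 10.6. Cluster 20, which mixes epithelial, endothelial and myeloid markers, had 29 in 34 WT cells (74.4 CPM) and 0 in 51 KO cells (upper bound 9.66 CPM), where 28.4 would be due if its cell mix were the same in both genotypes. Both groups together had 63 Batf3 UMIs in 103 WT cells (74.2 CPM) and 0 in 70 KO cells (upper bound 7.04 CPM). The WT level would give 38.9 there for the same cell mix, so the Batf3 count was lower in the KO cells of these groups. A 3′ count that fell outside the deleted part of the allele would not check the genotype, and which part was deleted is not given in the sources used here. Of its relatives and partners in T cells, Batf and Irf4 differed by less than 1.5-fold between genotypes in either fraction, and that list had median log2 ratios of -0.14 in CD45neg and -0.04 in CD45pos.

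Clustering gave 23 clusters. Naive-like cells, marked by lymph node homing and quiescence genes, were the most numerous class, and Th1-like, Th2-like, Th17-like, Treg-like, Tfh-like, interferon-like, proliferating and residency-like cells stood apart from them. Cluster 4 kept its number, with no member of a state or cell type list among its 10 leading genes. It did have Cxcr5, Sh2d1a, Tox2, Slamf6 and Cd200 of 12 Tfh genes raised, and 3 genes each of the naive, Th2 and Treg lists. Cluster 7 was led by killer lectin genes and Zbtb16, a transcription factor of innate-like T cells, shared Xcl1 and Atp8a2 among its 10 leading genes with cluster 15, and both stayed unnamed, as did the small cluster 18. The residency-like cluster took 89.7% of its 2442 cells from WT CD45neg, so it may be a state of that library rather than a cell type. Clustering again without the residency list and its 50 leading genes gave nearly the same shares, 23.1% of WT CD45neg and 2.11% of KO CD45neg. Each new cluster took the class that most of its cells had before, and genes that vary with the dropped ones remained. Similar shares were therefore likely, and they do not tell a state of that library from a cell type. Clusters of other cell types made up 0.226%, 1.59%, 0.288% and 1.16% of the libraries.

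**Figure D1:**
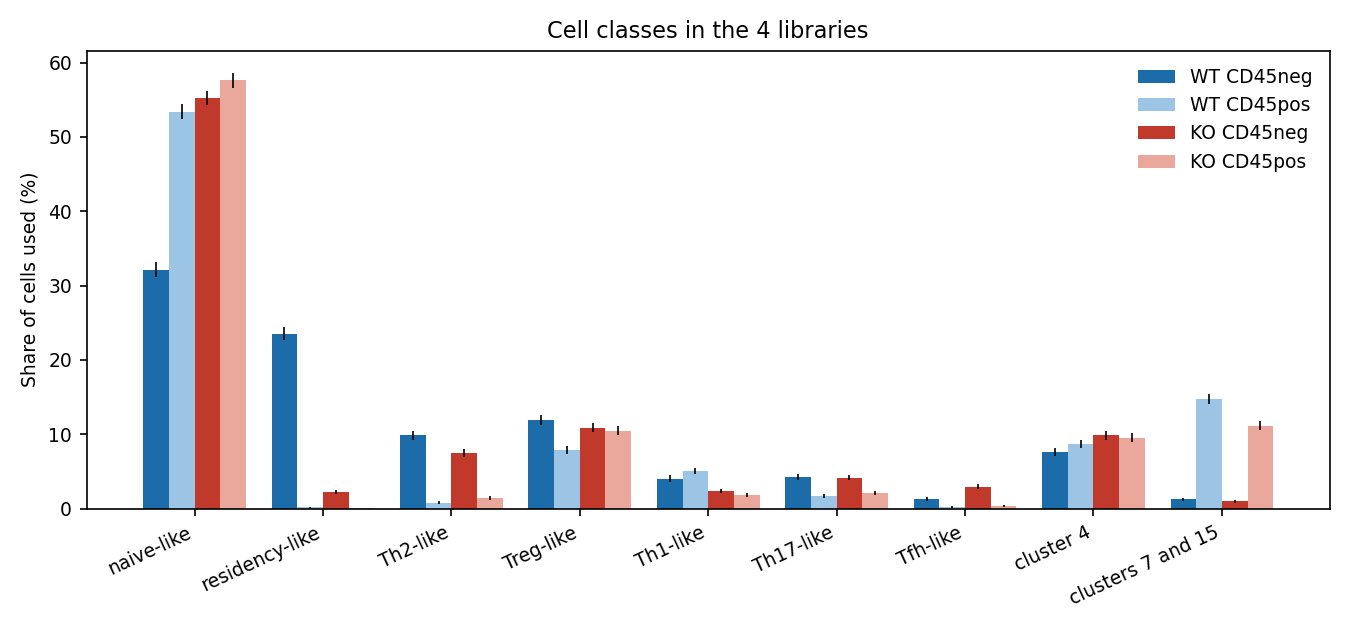
Share of the cells used (%) in each of 9 cell classes (horizontal axis) in the 4 libraries, 1 bar per library with its 95% Clopper-Pearson interval. Residency-like cells reach 23.5% in WT CD45neg and 2.22% in KO CD45neg, while naive-like cells stand at 32.2% and 55.3%.

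The comparison of CD45neg with CD45pos cells in wild-type mice asks what sets T cells in lung tissue apart from those in its blood. Tissue cells were richer in memory and effector states. Residency-like cells made up 23.5% (22.7 to 24.4) of CD45neg and 0.162% (0.0926 to 0.263) of CD45pos cells, Th2-like cells 9.88% and 0.809% (12.2-fold, 9.70 to 15.5), and Tfh-like cells 1.28% and 0.202% (6.32-fold). Th17-like cells were 2.49-fold and Treg-like cells 1.51-fold more frequent in tissue. Naive-like cells made up 32.2% (31.2 to 33.1) of tissue and 53.4% (52.4 to 54.4) of circulating cells, and clusters 7 and 15 were 11.9-fold less frequent in tissue. Th1-like cells differed less, with 4.03% and 5.04%. Among T cells outside the naive-like clusters, Treg-like shares were close (17.6% in both fractions) and Th1-like cells were 1.88-fold less frequent in tissue (5.96% against 11.2%).

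Gene levels over the pooled T cells went with this, and such pooled ratios mix the share of each cell class with the level within it. Pparg, a nuclear receptor of tissue Th2 cells, was 12.1-fold higher in WT CD45neg (40.5 against 3.35 CPM, 10.3 to 14.2). Rbpj, the DNA-binding partner of Notch, was 5.93-fold higher (256.8 against 43.3 CPM, 5.67 to 6.21). Sdc4, a cell surface proteoglycan, was 17.2-fold higher, and Hlf, Gm13481, Cxcl2, Cpd, Itsn1, Ltb4r1, the leukotriene B4 receptor, and Pard3, a polarity protein, were between 6.37-fold and 9.06-fold higher. The remaining pair among the 12 highest owed much of its ratio to single barcodes. For Scgb1a1, a club cell secretory protein, 91.7% of the UMIs in WT CD45neg came from 1 barcode, and for Ccl1, 74.9% did. Without the top cell of each library both stayed higher in tissue, at log2 ratios of 1.98 for Scgb1a1 and 2.72 for Ccl1. Among the 12 lowest were genes of cytotoxic and innate-like lymphocytes. Klrc1, Cd160, Klrb1c (11.4-fold lower), Gzma (7.55-fold), Il12rb2, a chain of the interleukin-12 receptor (7.02-fold), and Gzmb (6.43-fold) led them, and Xcl1, Plac8, Atp8a2, Slamf7, Zbtb16 and Gcnt2 were between 4.38-fold and 5.49-fold lower. Without clusters 7, 15 and 18, 2 of these 12 stayed among the 12 lowest, Xcl1 (log2 1.29) and Gcnt2 (0.80) were instead higher in tissue, and Plac8 (0.20) and Atp8a2 (0.40) did not pass the 1.5-fold bound.

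The fixed lists described the same contrast in WT. Of 12 Th2 genes, 10 were at least 1.5-fold higher in tissue and 1 lower, with a median log2 ratio of 1.86. Il5 stood at 7.46 against 0.248 CPM (30.2-fold, 17.3 to 57.4) and Il1rl1, the interleukin-33 receptor, was 4.06-fold higher, while Il4 was 2.01-fold lower. Of 9 Th17 genes, 7 were higher and 0 lower (median 1.63), with Il17a at 8.28-fold and Il1r1 at 5.17-fold. Of 13 Treg genes, 7 were higher and 1, Lrrc32, lower (median 0.62), with Foxp3 at 1.71-fold and Il2ra at 2.31-fold. Of 11 residency genes, Cxcr6 (1.87-fold), Rgs1 (2.02-fold) and Rbpj were higher and 0 lower, at a median of 0.26 (0.18 to 0.32, percentile 99.3 of random lists). That median was 0.13 with TMM scaling, 0.55 with every cell weighing the same and 1.11 without clusters 7, 15 and 18. Cd69, Itgae and Itga1 were not apart by 1.5-fold. Itga1 also marks clusters 7 and 15, and without clusters 7, 15 and 18 it joined the 12 genes highest in WT tissue, as did Cxcr6. Of 11 naive and central memory genes, Ccr7 (1.97-fold), Klf2 (1.75-fold) and Satb1 (1.74-fold) were lower and 0 higher (median -0.38). The Th1 list was mixed, with 3 of 12 higher, among them Cxcr3, and 5 lower, among them Ccl5 (2.81-fold) and Il12rb2, so that its median was 0.05 and its mean -0.38. Of 10 proliferation genes 8 were lower (median -0.92), Mki67 and Top2a among them. Of 8 Tfh genes Pdcd1, Tox2 and Angptl2 were higher (median 0.10), and of 11 interferon response genes Isg20 and Slfn5 were (median -0.10).

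Receptor lists also leaned to the tissue side in WT. Of 19 chemokine and homing receptors, 7 were higher, including Ccr8 (10.9-fold), Ccr4 (2.54-fold) and Ccr2 (2.47-fold), and Ccr7, Ccr9 and Ccr10 were lower (median 0.24). Of 16 cytokine and alarmin receptors, 6 were higher, including Il17rb (5.78-fold), and Il2rb was lower (median 0.34). Of 12 costimulation and checkpoint genes, 5 were higher and 0 lower (median 0.49), with Pdcd1, which encodes PD-1, at 5.07-fold and Cd40lg at 2.11-fold. Fkbp5 and Ddit4 of the glucocorticoid list were higher and Zbtb16 lower (7 genes, median -0.01). Immediate early and dissociation genes, which tissue handling can raise, were higher for 5 of 13 genes, Fosb at 2.85-fold, and lower for 0 (median 0.31). Within classes the median of this list was -0.255 in naive-like, -0.291 in Th1-like, -0.213 in Th17-like, -0.201 in interferon-like and -0.073 in cluster 4 cells. It was 0.004 in clusters 7 and 15 and 0.288 in Treg-like cells, so the pooled rise was not shared by every class. TMM scaling shifted the median of all ranked genes by -0.13 in this comparison.

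The same comparison in KO mice asks which of these differences stood without Batf3. Fewer cell classes were apart. Residency-like cells made up 2.22% (1.95 to 2.52) of KO CD45neg and 0.0541% (0.0176 to 0.126) of KO CD45pos cells. Th2-like cells were 5.42-fold (4.48 to 6.59), Tfh-like cells 8.49-fold (5.89 to 12.6) and Th17-like cells 1.97-fold more frequent in tissue, and clusters 7 and 15 were 11.4-fold less frequent. Naive-like cells made up 55.3% (54.3 to 56.2) of tissue and 57.7% (56.6 to 58.7) of circulating cells. Treg-like cells made up 10.9% and 10.5%.

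Pparg was again among the genes highest in KO tissue (6.46-fold, 38.2 against 5.91 CPM), with Zeb2, a transcription factor of terminal effector cells (7.03-fold), Gm13481, Pard3, Hlf, Ltb4r1 and Tnfsf11, which encodes RANKL (3.52-fold). Gpm6b, Pdcd1, Cish, an inhibitor of cytokine signalling, and Il1rl1 were between 2.32-fold and 3.10-fold higher. Scgb1a1 was 5.03-fold higher. Klrc1 (17.1-fold), Klrb1c (14.6-fold), Klrc2 (13.9-fold), Xcl1, a chemokine whose receptor is carried by type 1 dendritic cells (10.6-fold), and Cd160 (10.4-fold) were lowest, and Plac8, Gzmb, Zbtb16, Gm36723, Atp8a2, Il12rb2 and Gcnt2 were between 6.61-fold and 8.97-fold lower. Without clusters 7, 15 and 18, 0 of these 12 stayed among the 12 lowest, and Atp8a2, Gm36723 and Gcnt2 were no longer lower in tissue at all.

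Of 11 Th2 genes, 7 were higher in KO tissue and 1, Il4, lower (median 1.02), with Ccr8 at 3.49-fold and Il1rl1 at 2.32-fold. Of 9 Th17 genes 6 were higher and 0 lower (median 0.72), Il17a at 1.80-fold and Il23r at 1.88-fold. Of 9 Tfh genes 5 were higher and 0 lower (median 0.88), Sostdc1 at 29.8-fold (15.6 against 0.525 CPM, 19.7 to 47.3), but with members at 20 CPM or more the Tfh median was -0.029, so its direction rests on members with low counts. Of 11 residency genes only Rbpj was higher (2.06-fold) and only Itga1, a collagen-binding integrin, lower (4.78-fold), with a median of -0.08 (-0.11 to -0.01). Itga1 also marks clusters 7 and 15, which were less frequent in KO tissue, and its ratio without them is not reported here. That median was 0.50 without clusters 7, 15 and 18, and Cxcr6 then joined the genes ranked highest in KO tissue. Of 10 Th1 genes 8 were lower and 0 higher (median -1.04), with Ifng at 2.45-fold and Ccl5 at 3.86-fold lower, and without the same clusters the median was 0.06. None of 11 naive and central memory genes passed the rule (median 0.04, mean -0.03). Il2ra, Nrp1 and Itgb8 of 13 Treg genes were higher (median 0.23), none of 11 interferon response genes passed (median -0.19), and 9 of 10 proliferation genes were lower (median -0.88). Of 13 dissociation genes 4 were higher (median 0.11, but -0.22 with members at 20 CPM or more and -0.17 with all cell types). Of the receptor lists, 3 of 19 chemokine and homing receptors were higher and 4 lower (median -0.11, but 0.11 without clusters 7, 15 and 18), 5 of 16 cytokine receptors higher and 1 lower (median 0.08), and Pdcd1 and Cd40lg of 11 checkpoint genes higher (median 0.13). The glucocorticoid list had 2 higher and 1 lower of 7.

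The comparison of KO with WT in CD45neg cells addresses the question of the series most directly. Residency-like cells were 10.6-fold less frequent in KO tissue, 2.22% (231 of 10406 cells) against 23.5% (2190 of 9306), a ratio with a counting interval of 9.25 to 12.2. The size of this ratio depends on the clustering, and at resolution 0.6 it was 3.45-fold (9.72% against 33.5%). Naive-like cells were 1.72-fold more frequent, and among T cells outside the naive-like clusters the residency-like share was still 4.99% against 34.8%. Th1-like cells were 1.70-fold less frequent (2.36% against 4.03%), but not by 1.5-fold outside the naive-like clusters (5.32% against 5.96%). Tfh-like cells were 2.30-fold more frequent (2.94% against 1.28%, 1.86 to 2.87). Outside the naive-like clusters Tfh-like cells were 306 of 4626 T cells in KO and 119 of 6292 in WT, a larger contrast. Th2-like cells (7.45% against 9.88%), Th17-like cells (4.15% against 4.26%) and Treg-like cells (10.9% against 11.9%) differed by less than 1.5-fold. Within the Treg-like class, cluster 12 made up 8.10% of WT and 3.58% of KO cells, and cluster 8 made up 2.36% and 4.58%.

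Residency genes were lower in KO tissue. Cxcr6 (ENSMUSG00000048521, chromosome 9, 123806477 to 123811754), the receptor for Cxcl16, was 2.93-fold lower (61.9 against 181.5 CPM, 2.81 to 3.06), and Rbpj was 3.40-fold lower (75.5 against 256.8 CPM, 3.27 to 3.54). Itga1 (6.53-fold), Prdm1, which encodes Blimp-1 (1.80-fold), Rgs1 (1.79-fold) and P2rx7, an ATP-gated channel (1.67-fold), were lower too. That made 6 of 11 residency genes lower and 0 higher, with a median log2 ratio of -0.72 (-0.81 to -0.61), below all random lists. Cd69 (107.4 against 137.5 CPM) and Itgae (11.9 against 9.83 CPM) were not apart by 1.5-fold. Cxcr6 UMIs were found in 24.3% of WT and 8.92% of KO CD45neg T cells thinned to 2000 UMIs (32.1% and 13.2% before thinning). In naive-like cells, which should lack Cxcr6, thinned shares were 0.370% in both libraries, at median depths of 4560 and 4479.5 UMIs before thinning. Rbpj UMIs were found in 30.8% and 11.4% of thinned cells (40.9% and 20.1% unthinned), against 4.37% and 4.96% of naive-like cells.

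Th1 genes were lower as a group in KO tissue, 8 of 12 with 0 higher (median -1.36). Ifng, the Th1 cytokine, was 3.60-fold lower (11.1 against 40.0 CPM, 3.26 to 3.99), Tbx21, which encodes T-bet, 2.83-fold, the chemokine receptor Cxcr3 3.04-fold, Ccl5 3.20-fold and Ccl4 15.6-fold (0.509 against 7.93 CPM, 10.3 to 24.7). Of 12 Th2 genes 4 were lower, namely Il5 (3.42-fold, 2.19 against 7.46 CPM), Ccr8 (3.08-fold), Calca (2.65-fold) and Cd200r1 (1.66-fold), and Areg, which encodes amphiregulin, was 1.51-fold higher (median -0.40). Gata3, Il1rl1 and Pparg, at 38.2 against 40.5 CPM, did not pass. Naive and central memory genes lay higher, at a median of 0.49 (0.46 to 0.54), with Ly6c1 at 1.52-fold and Lef1 (1.47-fold) and Ccr7 (1.40-fold) under the 1.5-fold bound. Slamf6, Sostdc1 (6.04-fold, 4.87 to 7.56) and Cd200 of 9 Tfh genes were higher and Pdcd1 was 1.73-fold lower (median 0.14). Ltb4r1 was the 1 Th17 gene of 9 lower (median -0.29) and Lrrc32 the 1 Treg gene of 13 higher (median -0.13). Isg20 alone of 11 interferon response genes was lower (median -0.16), and none of 10 proliferation genes passed (median -0.15). Of 18 chemokine and homing receptors, 6 were lower, among them Ccr2 (2.30-fold), Ccr8, Cxcr3, Cxcr6 and Cd44 (1.85-fold), and Ccr10 was higher (median -0.29). Pdcd1 and Havcr2 of 12 checkpoint genes were lower (median -0.26), as were Il2rb and Il18rap of 16 cytokine receptors and Zbtb16 of 7 glucocorticoid genes (median -0.21). Fosb, Hspa1b and Atf3 of 13 dissociation genes were lower and none higher in KO tissue, while 10 did not pass (median -0.35, -0.42 to -0.27, below all random lists).

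**Figure D2:**
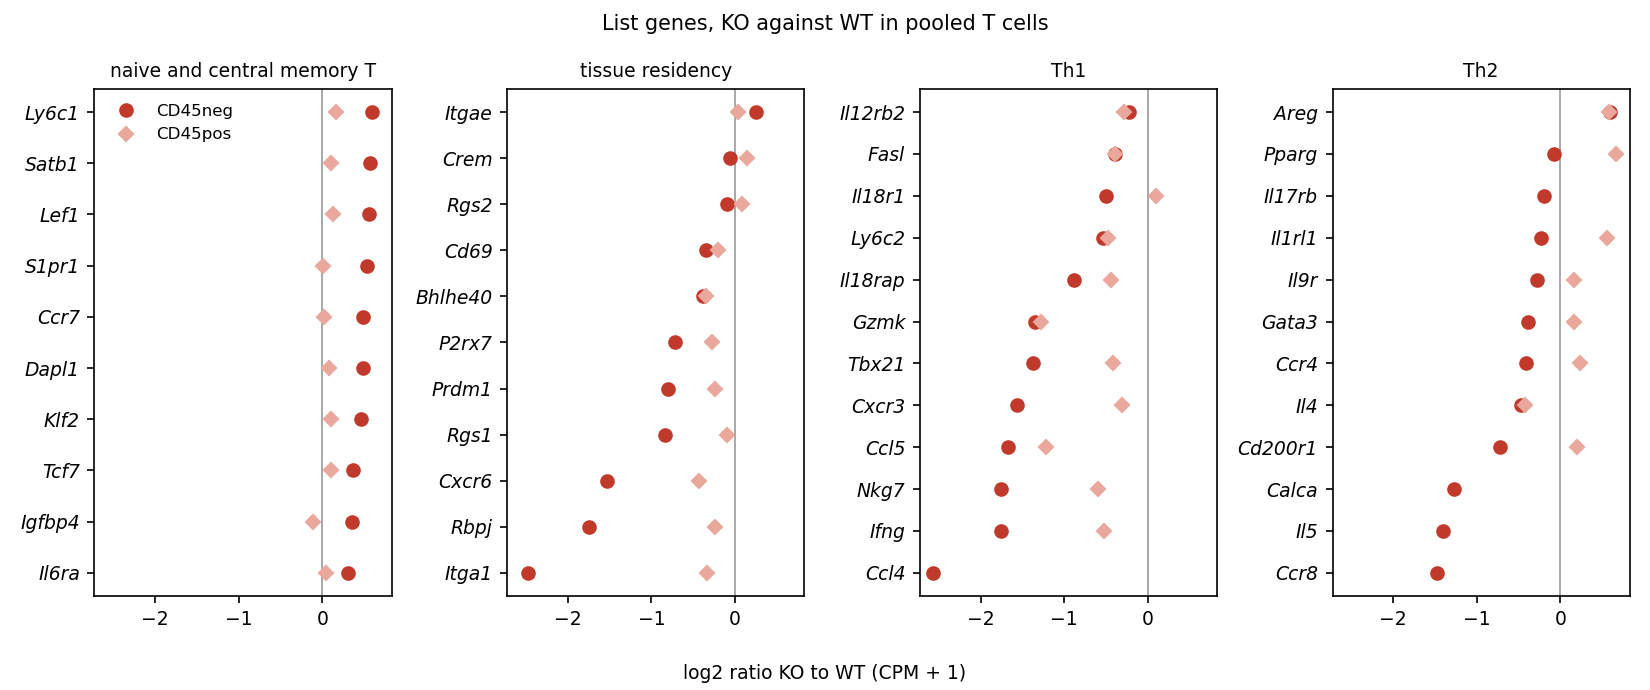
log2 ratio of KO to WT (CPM plus 1, horizontal axis) of genes of 4 fixed lists in the pooled T cells, with circles for CD45neg and diamonds for CD45pos. The residency list has a median of -0.72 in CD45neg and -0.24 in CD45pos, and the Th1 list -1.36 and -0.44.

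By rank, the lowest genes in KO CD45neg were Ifi213 (53.6-fold lower, 0.700 against 37.5 CPM, 38.0 to 78.2) and Ifi206 (10.5-fold lower, 9.34 to 11.8), of the interferon-inducible p200 family. Itga1, Mmp9, a secreted gelatinase (4.91-fold), Itsn1, Ifng, Rbpj, the cytotoxic granule gene Nkg7 (3.42-fold), Hip1 and Fgl2, an immunoregulatory fibrinogen-like protein (3.38-fold), followed. Scgb1a1 and Ccl1 completed the 12. Without the barcode that held most of its UMIs, Scgb1a1 was higher in KO (50.8 CPM in WT and 86.8 in KO, log2 0.76), and Ccl1 stayed lower at a log2 ratio of -0.92. The 12 highest were at most 1.77-fold higher. They were Dusp10, a phosphatase of stress kinases (512.4 against 294.0 CPM), Gm14085, Auts2, Lypd6b, Slc15a2, Tubb2a, Klhdc2, Slamf6, Gpm6b, Sh3bp5, Patj and Rflnb. Gm14085, Auts2, Tubb2a and Klhdc2 were among the 10 leading genes of naive-like clusters, a class more frequent in KO CD45neg. Gpm6b was among those of cluster 4 and the Tfh-like cluster. How much of these folds reflects composition was not separated.

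In CD45pos cells the comparison of KO with WT asks whether circulating T cells differed as well. The differences were smaller, with a standard deviation of log2 ratios over ranked genes of 0.141 against 0.241 in CD45neg. Residency-like cells were few, 5 in KO and 16 in WT, and 2.99-fold less frequent in KO (1.05 to 10.4), but at resolution 0.6 they were 1.45-fold more frequent in KO. Naive-like cells (57.7% against 53.4%) differed by less than 1.5-fold. Th1-like cells were 2.75-fold less frequent in KO (1.83% against 5.04%, 2.31 to 3.30) and Th2-like cells 1.70-fold more frequent (1.38% against 0.809%). Treg-like cells made up 10.5% in KO and 7.90% in WT, and clusters 7 and 15 made up 11.2% and 14.8%.

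Gzma, a granzyme of cytotoxic cells, was 23.1-fold lower in KO CD45pos (1.21 against 28.0 CPM, 17.6 to 31.0), and the chemokine Ccl5 was 2.33-fold lower (462.8 against 1076 CPM, 2.29 to 2.36). Ifi213 was 52.5-fold and Ifi206 8.64-fold lower, and Plac8, Gas5, a host gene of small nucleolar RNAs, Ifi209, Ifi208, Xcl1, Cd48, Atf6 and Cdk8 were between 1.55-fold and 1.86-fold lower. Among the 12 highest, only Aim2, a sensor of cytosolic DNA (1.57-fold), and Areg (1.51-fold) passed the 1.5-fold bound. Il1rl1 (1.49-fold), Plcb4, Nav2, Tnfrsf4, Myo1e, Izumo1r, Siah3, Nebl, Dusp10 and Slamf6 (1.32-fold) did not.

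Of 11 Th1 genes Ccl5, Nkg7 (1.51-fold) and Gzmk (3.21-fold) were lower and 0 higher in KO CD45pos (median -0.44). None of 11 residency genes passed (median -0.24), with Cxcr6 at 71.5 against 97.0 CPM, and none of 11 naive and central memory genes did (median 0.07). Pparg (1.76-fold) and Areg of 8 Th2 genes were higher (median 0.22), as were Il23r (1.88-fold) and Ccr6 (1.71-fold) of 6 Th17 genes (median 0.25). None of 12 Treg genes passed (median 0.26), nor did any of 7 Tfh genes (median -0.01, mean 0.03), 11 interferon response genes (median -0.05), 10 proliferation genes (median -0.18), 11 checkpoint genes (median 0.08), 14 cytokine receptors (median 0.05) or 7 glucocorticoid genes. Ccr6 was higher and Ccr9 lower among 18 chemokine and homing receptors (median -0.05). Hspa1a (3.36-fold) and Hspa1b (2.87-fold) of 12 dissociation genes were lower (median -0.09).

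Set against each other, the genotype ratios in tissue and in circulation differed for several lists. The median difference of log2 ratios, tissue minus circulation, was -0.45 (-0.57 to -0.29) for residency genes, -0.70 for Th2, -0.66 for Th17, -0.53 for Th1 and -0.33 for Treg genes, and 0.43 (0.41 to 0.47) for naive and central memory genes. It lay near 0 for interferon response (-0.07) and proliferation genes (0.01), and was 0.09 for Tfh genes. Chemokine and homing receptors differed by -0.31, checkpoint genes by -0.31 and cytokine receptors by -0.32. T cells outside the naive-like clusters made up 67.6% of WT and 44.5% of KO CD45neg cells, against 45.0% and 41.2% of CD45pos cells. These pooled differences therefore mix composition with level. The part due to each was not separated, so they do not show an effect on any 1 of these programmes.

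Within classes, KO and WT tissue cells were closer in residency genes than over all T cells. Residency genes were not left out of the clustering, and some of them lead the residency-like class. The other classes are therefore closer in these genes partly by construction, and the medians cannot tell a difference in level from one in composition. The median log2 ratio of the residency list was -0.15 in Th2-like, -0.15 in Th1-like, -0.20 in Th17-like, -0.18 in Tfh-like and -0.32 in Treg-like cells, where it was -0.05 in cluster 12 alone. Treg-like cells of KO tissue had Rbpj 3.58-fold, Mmp9 4.21-fold and the metallothionein Mt1 5.91-fold lower, and Hdac9 and Trat1, a T-cell receptor adaptor, 2.75-fold and 2.45-fold higher. These folds include the different mix of clusters in that class, and in cluster 12 alone Rbpj was 2.33-fold and Mt1 4.18-fold lower and Trat1 3.03-fold higher. Th2-like cells had Nkg7 4.55-fold and Cxcl2 3.10-fold lower and Slamf6 4.80-fold and the egress receptor S1pr1 2.87-fold higher. The Th1 list had medians of -0.88 in Treg-like cells (-0.62 in cluster 12 alone), -1.07 in Th2-like, -1.02 in interferon-like, -1.10 in Tfh-like, -0.25 in Th1-like, -0.44 in Th17-like, -0.48 in cluster 4, -0.06 in residency-like, 0.15 in cluster 7 and 15 and, on 3 members, 0.05 in naive-like cells. Differences between classes were not tested. Th1-like cells of KO tissue had Ccl5 2.46-fold (2704 against 6645 CPM), Gzmk 2.55-fold and Zeb2 3.59-fold lower and Hdac9 3.01-fold and Ikzf2, which encodes Helios, 2.29-fold higher. In CD45pos Th1-like cells, Gzma was 62.9-fold lower (5.45 against 342.9 CPM, 24.5 to 232) and Zeb2 7.96-fold. Naive and central memory genes had medians of 1.15 in residency-like (on 231 KO and 2190 WT cells), 0.75 in Treg-like, 1.00 in Th2-like, 0.70 in Th17-like, 0.71 in cluster 7 and 15, 0.36 in Th1-like, 0.30 in Tfh-like, 0.26 in cluster 4, 0.04 in naive-like and -0.02 in interferon-like cells. Th17-like cells had Il22 4.24-fold higher (61.2 against 14.4 CPM, 2.72 to 6.88).

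Several of the genes named for the genotype lie near each other on chromosome 1, as Batf3 does. Of 5446 genes at 20 CPM with a position, 13 were at least 1.5-fold apart the same way in both fractions, and 7 of these (53.8%) start at 155096367 or beyond on chromosome 1, where 1.98% of all the genes do. These were Ifi206, Ifi208, Ifi209, Ifi213, Cd48, Atf6 and Xcl1, all lower in KO, and the others were Zeb2, Dusp2, Plac8, Nkg7, Ccl5 and Gzma. In naive-like cells 9 genes were apart in this way and 7 (77.8%) lie there, among them Gas5 (422.1 against 703.3 CPM in CD45neg) and, higher in KO, Aim2 (51.5 against 29.9 CPM). Dusp10 and Slamf6 start in the same stretch, at 184034381 and 171917458. The fixed list of genes next to Batf3 had medians of 0.08 (mean -0.01) in CD45neg and 0.01 in CD45pos, with Atf3 (1.59-fold) lower among 13 in CD45neg and none among 12 in CD45pos.

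**Figure D3:**
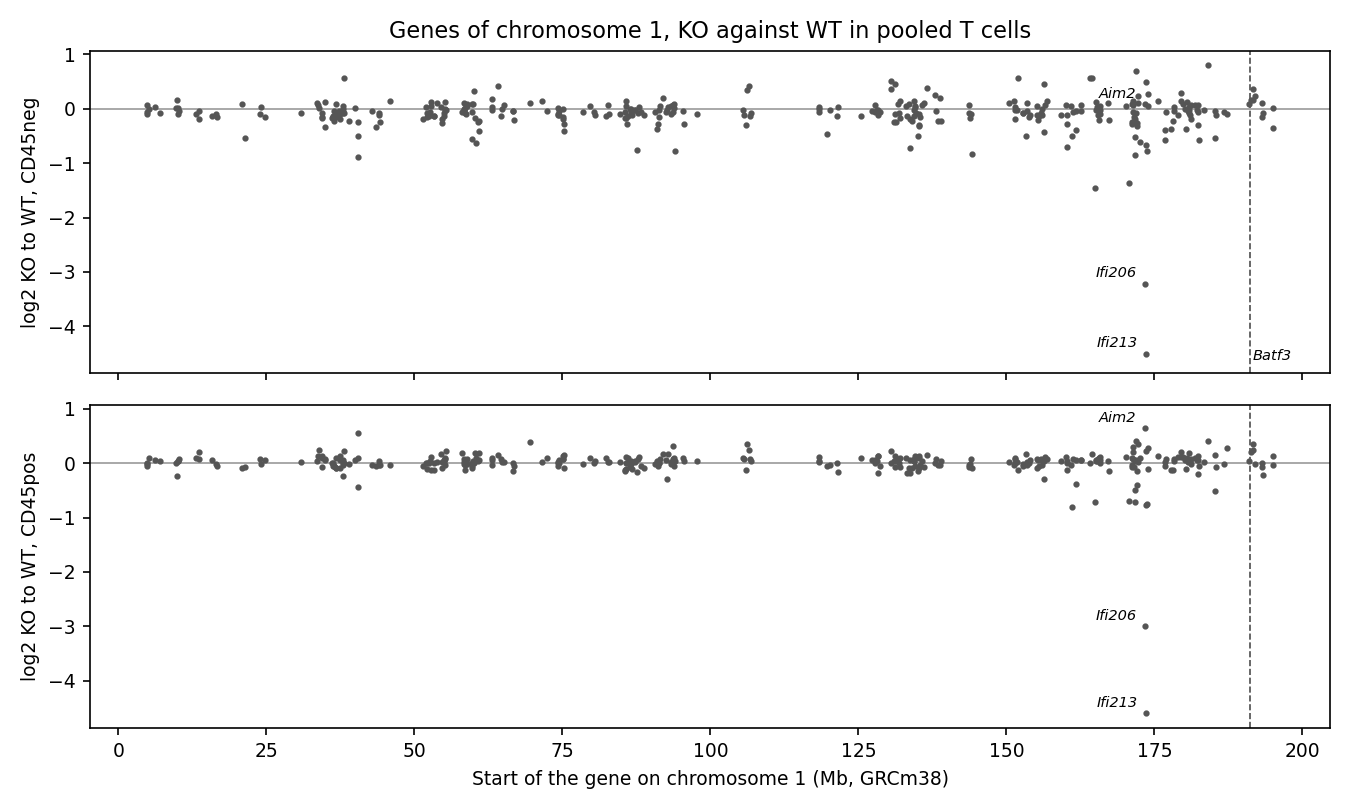
log2 ratio of KO to WT (vertical axis) against the start of each chromosome 1 gene in Mb (horizontal axis, GRCm38), CD45neg above and CD45pos below, 1 point per gene and a dashed line at Batf3. Ifi213 and Ifi206 lie lowest in both panels, at -4.50 and -3.22 in CD45neg.

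The antibody tags did not separate the cell classes. Mean CD103 tag counts were 184.7 in WT CD45neg, 119.6 in WT CD45pos, 148.0 in KO CD45neg and 100.4 in KO CD45pos, and CD69 counts were 123.1, 79.0, 94.8 and 63.3. All 6 tags ordered the libraries this way, APC and PE included. In WT CD45neg the CD44 tag averaged 163.7 in naive-like and 178.9 in residency-like cells, while its gene Cd44 stood at 18.1 and 446.1 CPM. Across cells of a library, a tag correlated with its own gene at r between -0.0908 and 0.0949 and with the sum of the other tags at r between 0.852 and 0.932 (across cells, which are not independent replicates). Over 1 threshold per antibody, 96.1% of WT CD45neg cells were CD103-positive, against 25.3% of WT CD45pos, 78.2% of KO CD45neg and 5.15% of KO CD45pos cells. With a threshold per library the order changed, so that WT CD45neg lay lowest and KO CD45pos highest. The shares were then 59.4% of WT CD45neg, 60.8% of WT CD45pos, 95.9% of KO CD45neg and 96.9% of KO CD45pos cells.

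**Figure D4:**
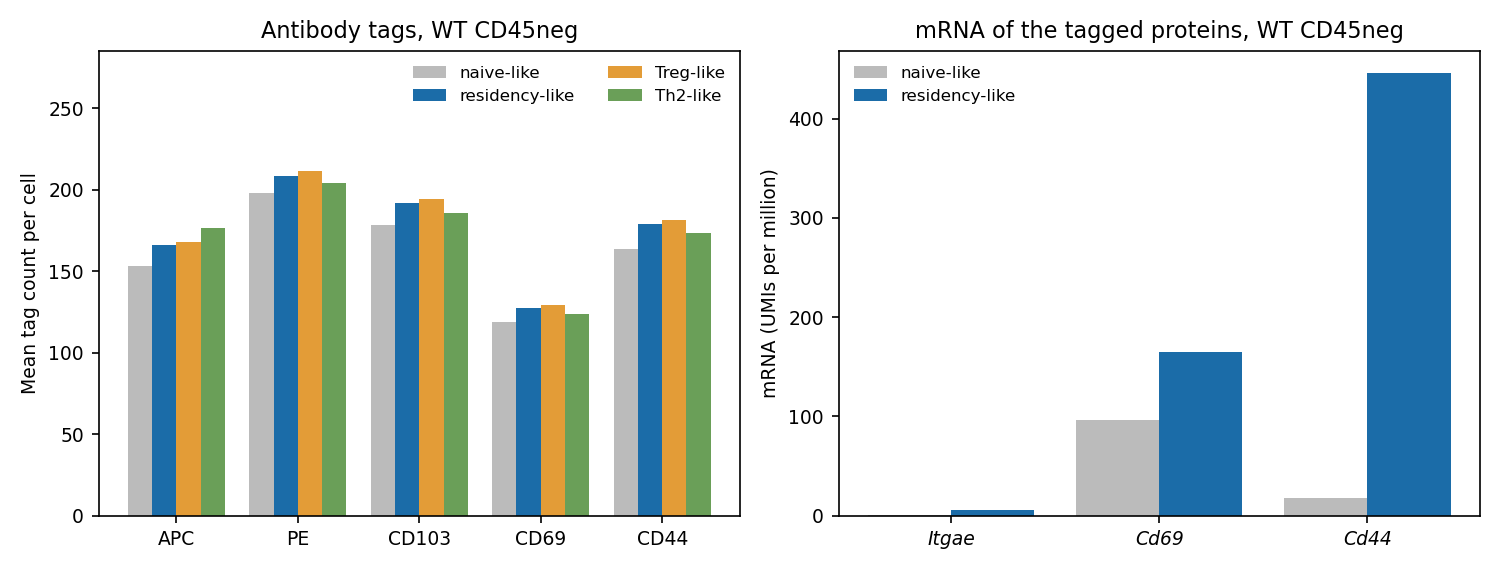
Left, mean tag count per cell of 5 antibodies in 4 cell classes of WT CD45neg, and right, mRNA (CPM) of 3 tagged proteins in naive-like and residency-like cells, 1 bar per class. The CD44 tag is close between these classes (163.7 and 178.9) while Cd44 is not (18.1 and 446.1 CPM).

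Markers of other cell types were few but not equal between libraries. Summed over all filtered cells, the monocyte and macrophage list stood at 206.6 CPM in WT CD45neg, 455.5 in WT CD45pos, 213.3 in KO CD45neg and 298.3 in KO CD45pos, and the dendritic list at 30.6, 217.6, 30.1 and 130.6. The epithelial list stood at 2792, 18.6, 707.1 and 24.1, and at 643.7, 17.4, 102.9 and 24.0 in pooled T cells alone, where 20719 of the 23631 UMIs of WT CD45neg were Scgb1a1 in 1 barcode. Scgb1a1 was otherwise spread thinly, with a UMI in 13.9% of WT CD45neg, 3.29% of WT CD45pos, 13.6% of KO CD45neg and 3.48% of KO CD45pos T cells, and in 12.2% to 14.8% of the naive-like, residency-like, Th2-like and Treg-like cells of WT CD45neg, the even pattern of background RNA. Killer and innate lists were higher in circulation. In T cells the NK list had median log2 ratios of tissue to circulation of -2.78 in WT and -3.12 in KO, the CD8 T list -1.11 and -1.42, and the gamma-delta T list -1.10 and -1.35, while the ILC2 list, which shares Gata3 and Il1rl1 with Th2 cells, leaned to tissue, with 1.19 in KO. For KO against WT in CD45neg these lists had medians of 0.51 (1 NK gene), -0.58, -0.51 and -0.24. B (134.7 against 111.7 CPM), plasma (28.9 against 32.9 CPM) and endothelial genes (263.8 against 194.4 CPM) differed by less than 1.5-fold between KO and WT CD45neg. Neutrophil, mast and basophil, and stromal lists stayed under 2 CPM in every library. The erythroid and platelet list stood at 23.3 CPM in KO CD45neg and 3.19 in WT CD45neg, and all Hbb-bs UMIs among KO CD45neg T cells came from 3 cells.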

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

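The tests of explanations in this part were chosen after the results they address were seen. The genes below stood at least 1.5-fold apart in opposite directions in a pair of parallel comparisons, and with 1 library per group none of these opposite differences was tested.

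Cxcr3, a receptor that guides Th1 cells, was higher in tissue than in circulation in WT (log2 0.60) and lower in KO (-0.65). Lgals3, a galectin, went the same way (0.68 in WT and -0.63 in KO), as did the gelatinase Mmp9 (0.83 and -0.83). Cxcl2, a neutrophil chemokine, was lower in KO than in WT in CD45neg (-0.65) and higher in CD45pos (0.52). Scgb1a1 was lower in KO CD45neg (-2.69) and higher in KO CD45pos (0.56). Without the barcode that holds most of its UMIs its ratio in CD45neg was 0.76, so the opposite direction rests on 1 barcode.

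The lower share of residency-like cells in KO CD45neg is the first pattern weighed. Blood cells carried over into that sort are argued against only if they had the class mix of CD45pos cells, which was not checked. Clusters 7 and 15, picked because they lie mostly in CD45pos, reached 8.79% (7.10 to 10.8) of their CD45pos share in KO CD45neg. They reached 8.38% in WT, and carry-over with that mix would need 90.6% in KO to give the pattern. Dilution by naive-like cells is argued against by a KO to WT ratio of 0.143 (0.125 to 0.164) among the other T cells, and unequal depth by a ratio of 0.108 (0.0947 to 0.124) in cells thinned to 1 depth. A difference between the mice or sorts other than genotype cannot be told apart from an effect of Batf3, with 1 library per group. Loss of Batf3-dependent dendritic cells is the biological explanation the design names, and it stays open and untested.

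The genes of distal chromosome 1 that were apart in both KO libraries are the second pattern. DNA of the strain in which the allele was made, kept around the targeted gene through crosses to the WT strain, is a candidate explanation. It stays open, since the share of genes there (53.8% of those apart in both fractions, against 1.98% of all) is what defined the pattern. The list next to Batf3 fixed beforehand had medians of 0.08 in CD45neg and 0.01 in CD45pos, with 0 of 11 members apart in both. That list cannot decide the question. Over the whole stretch 7 of 108 genes were apart, so few of 11 would be due, and a median can hide genes that move in opposite directions. A large fall of the interferon response is argued against by the size of its list median, -0.16 (-0.22 to -0.10) in CD45neg and -0.05 in CD45pos. A small fall in the pooled cells is not excluded, since both medians lie below 0. In naive-like cells the list medians were -0.015 in CD45neg and 0.18 in CD45pos. Whether strain variants change the RNA level or only the matching of reads was not tested, and an effect of Batf3 itself on these genes stays open.

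The third pattern is the lack of contrast in the antibody tags. Free antibody in the droplets may make up most tag counts, since the mean count of 1 tag had a ratio of 0.903 between naive-like and residency-like cells in WT CD45neg and each tag correlated with the others at r between 0.852 and 0.932. No biological explanation was tested for the tags.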

How the results depend on the processing

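The pools without clusters 7, 15 and 18, the pools without the top cell of a gene, Treg-like cells of cluster 12 alone, the clustering without residency genes and the shares outside naive-like clusters were chosen after seeing the data. Where a value below differs, the cause was not tested.

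With every cell weighing the same, the residency list had a median of 0.55 for tissue against circulation in WT, 0.046 in KO (reversed), -0.89 for KO against WT in CD45neg, -0.28 in CD45pos and -0.61 for the difference. The naive list had 0.70 for KO against WT in CD45neg and -0.042 for tissue against circulation in KO (reversed). With TMM scaling, the residency list had 0.13 in WT and -0.11 in KO for tissue against circulation, the naive list 0.56 for KO against WT in CD45neg, and the sex-linked difference 0.032 (reversed). Without clusters 7, 15 and 18, the residency list had 1.11 in WT and 0.50 in KO (reversed) for tissue against circulation, -0.073 for KO against WT in CD45pos and -0.71 for the difference. Also reversed there were, in WT, Xcl1 (1.29), Plac8 (0.20), Atp8a2 (0.40), Gcnt2 (0.80) and the interferon list (0.029), and, for CD45neg against CD45pos in KO: Atp8a2 (0.00813), Gm36723 (0.46), Gcnt2 (0.83) and the Th1 (0.056), naive (-0.052) and homing receptor lists (0.11).

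For tissue against circulation in KO, members at 20 CPM or more reversed the Tfh (-0.029) and stress lists (-0.22), and all cell types together the stress list (-0.17). The stricter filter reversed the proliferation list for KO against WT in CD45pos (0.0064). Without its top cell Scgb1a1 reversed in CD45neg (0.76).

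The residency-like share of WT CD45neg was 33.5% at resolution 0.6, 24.8% with doublets kept and 34.8% among T cells outside naive-like clusters, and that of KO CD45neg was 9.72% at resolution 0.6 and 4.99% outside naive-like clusters. In cluster 12 alone the residency list was at -0.053. The share of WT CD45neg over the CD103 threshold was 59.4% with a threshold per library and 98.5% after scaling. In all barcodes, the macrophage list stood at 466.6 CPM and Batf3 in WT CD45pos at 0.834 CPM. Among the further results, 94 kept their value with TMM scaling and 80 moved, 102 and 72 with equal weights, 134 and 41 with the looser filter, and 132 and 42 with the stricter one. Depth limits Batf3 in T cells, at 1 UMI or less per library.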

Other observations

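The test of the invariant natural killer T cell hypothesis had its bound set before its value was computed, although Traj18 counts and leading genes of these clusters had been seen. After thinning to 2000 UMIs, Gata3 UMIs were found in 22.8% of WT CD45neg, 12.9% of WT CD45pos, 18.2% of KO CD45neg and 15.04% of KO CD45pos T cells, and in 5.28%, 7.25%, 5.87% and 8.15% of their naive-like cells, so that part of these shares is not a mark of Th2 cells. Before thinning the shares for Gata3 were 33.7%, 27.6%, 28.6% and 27.2%. Foxp3 UMIs were found in 4.98% of WT CD45neg, 2.91% of WT CD45pos, 4.73% of KO CD45neg and 3.83% of KO CD45pos cells (7.34%, 5.67%, 7.69% and 6.57% before thinning), and Cxcr3 UMIs in 13.6%, 7.60%, 4.11% and 6.19% (20.4%, 15.9%, 7.26% and 11.7%). In naive-like cells Foxp3 stayed between 0.114% and 0.337% and Cxcr3 between 0.038% and 0.202%.

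Proliferating cells were more frequent in circulation than in tissue, with 2.19% against 0.784% in WT and 1.80% against 0.884% in KO. Interferon-like cells made up 2.41%, 3.47%, 2.30% and 2.44% of WT CD45neg, WT CD45pos, KO CD45neg and KO CD45pos cells. Cluster 18, with Th17 and gamma-delta genes and little Cd4, made up 0.645%, 0.101%, 0.461% and 0.0541%.

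Clusters 7 and 15 may hold invariant natural killer T cells, whose receptor uses the Trav11 segment. Trav11 gave 17.9% (13.1 to 23.5) of their Trav UMIs, 40 of 224, against 0.272% in naive-like cells. The interval spans the 20% set as the bound, so the test leaves this undecided. Zbtb16 stood at 438.4 CPM and Cd4 at 78.0 CPM in the pool of both clusters. The receptor segment Traj18 stood at 8.91 CPM there and did not set these clusters apart. Across the T-cell classes Traj18 ran from 3.34 CPM in naive-like cells to 13.2 in Tfh-like cells and 13.3 in cluster 18. Cluster 18 had Zbtb16 at 669.9 CPM and a Trav11 share of 17.6%, on 3 of 17 UMIs.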
